A study of Caenorhabditis elegans with 2 samples.

How the data were processed

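SOMI-1-eGFP ChIP-seq data from whole young adult C. elegans were used, with 2 biological replicates of 1 group, per the labels. Each replicate was a separate biological sample, per the labels. The files used were 4 peak lists in narrowPeak format on the ce11 assembly, per the labels. Per the text files deposited with the samples, the authors called 1 list on each replicate and 1 on both replicates together, each with 1 control alignment, and made the thresholded list from these with an irreproducible discovery rate (IDR) procedure. The control alignment was not analysed here. The aligner, the peak caller, their settings and the read depth are not given in the sources used here.

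The signal value of each peak was deposited by the authors as their peak caller gave it, and it is a number without a stated unit that is never negative. Signals were compared within a list only, except that the signals of the replicates' own lists at the same place were correlated. The −log10 q-value of each peak was deposited by the authors and was not used in any test, and the column for the p-value was left unset in the deposited lists. In the thresholded list the −log10 q-value ran from 2.57 to 3.43, and 1340 of the 1667 peaks stood at the highest value. The summit is the position the authors gave within each peak. All 1667 thresholded peaks were found as identical rows in the joint list, and they were the 1667 rows of highest signal there. Overlapping peaks occurred, since merging the 1667 peaks left 1600 regions.

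Genes came from the Ensembl release 115 annotation of WBcel235, the assembly that ce11 also names, and sequences from the RefSeq copy of it. All peaks ended inside the chromosome lengths of that copy. Positions are given 1-based. The 6 nuclear chromosomes were used, with 19973 protein-coding genes. A gene counted as bound if a thresholded summit lay from 1000 bp upstream to 200 bp downstream of the 5′ end of any of its annotated transcripts. Many transcripts of this organism are trans-spliced, so that an annotated 5′ end need not be the place where transcription starts. Places were assigned in the order promoter window, 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic, where intergenic means outside protein-coding genes and can include non-coding genes, and their random shares come from 200 placements.

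Summits were placed at random within their own chromosome 1000 times for the promoter share, the share in the middle 50% of the autosomes and the non-coding classes, with two-sided permutation p-values whose smallest value is 0.002. The X share was tested by a two-sided exact binomial test against length. Gene lists were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 20 lists, against all protein-coding genes. Non-coding genes were tested by class, with a summit within 500 bp. The plan for these classes named both a Fisher test and random placement. The permutation p was used, and 10 annotated classes were tested in place of the 5 groups of the plan. Intervals of shares are Wilson 95% intervals and cover counting error only. Peaks were treated as independent in all tests, so p-values can be too small where neighbouring peaks arise together. They describe these lists, not a population of animals. Merging overlapping peaks moved the exact binomial p of the X share from 5.86e-14 to 1.32e-13. It moved the adjusted Fisher's exact p of the ribosomal protein list from 6.09e-15 to 5.45e-15.

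Words of 6 bases, either strand counted as 1 word, were compared between the 101-bp window around the summit and windows centred 300 bp to either side. On chromosomes I, III and V the 40 words with the largest standardised excess were taken. On II, IV and X each was tested by a one-sided exact sign test of the summit window against a single flank, left and right in turn. Word shares over all chromosomes had been looked at before the number of 40 words was set and before GACGCA and the other plotted words were singled out, so these choices were not blind to the test chromosomes. GC-matched control windows were drawn from 60000 promoter positions farther than 1000 bp from any summit of the joint list, and the largest difference in GC content within a match was 7.92 percentage points.

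The gene lists and the rule for named genes were fixed before the data were examined. The lists were transgene markers, heterochronic genes, molting, microRNA machinery, cuticle collagens, epidermis and seam, intestine, muscle, pan-neuronal, germline, major sperm proteins, ribosomal proteins, histones, proteasome, mitochondrial respiration, heat shock and chaperones, nuclear hormone receptors, homeobox, translation factors and vacuolar ATPase. In the lists 3 names, let-7, ram-4 and daf-21, were not symbols of the annotation used and matched no gene by that name. The other microRNA genes of the heterochronic list were described, not tested, and let-7 was not examined. Named are the genes at the 20 strongest thresholded peaks or the nearest gene to such a peak, always somi-1, unc-119, lin-14, lin-29, bed-3 and mir-84, up to 4 bound members of each list with the strongest peak, and up to 4 genes of each of 5 non-coding classes (miRNA, tRNA, snoRNA, snRNA and ncRNA). Other genes named were chosen after their values were seen, such as lep-2 as the remaining bound heterochronic gene.

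The alternatives fixed before the data were examined were each replicate's own 1667 strongest peaks in place of the thresholded list, the stronger 833 thresholded peaks, the unthresholded joint list, other promoter windows and peak assignments, an expected X share from genes, placement within 5000 bp, a distance of 200 bp for non-coding genes, other word windows and flanks, and other definitions of overlap between replicates. Merging overlapping peaks, leaving out peaks near tRNA genes and GC-matched controls were added after the data were seen.

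The procedures were tested on simulated data. In 20 sets of 1600 random peaks, the promoter, X and centre tests passed 0, 1 and 1 times at 0.05. List calls were 2 of 400, class calls 0 of 200 and word calls 1 of 800. In a set of 1600 peaks with 6 planted features, all 6 were recovered, while 3 of 10 classes were called where 1 had been planted, and the reason for the others was not tested. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.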

Results

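Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the SOMI-1 protein sits on the genome of the nematode Caenorhabditis elegans. SOMI-1 is a zinc finger protein that was named after its role in animals that overexpress the microRNA mir-84. The animals were whole young adults of mixed sex, collected at 65.5 hours after synchronisation by larval starvation. They carried a transgene with somi-1 fused to green fluorescent protein (eGFP) and other tags, together with a working copy of unc-119 that rescues the unc-119 mutation of the strain. The fusion protein was precipitated with an antibody against GFP from sonicated chromatin with fragments of 200 to 800 bp. There was 1 group with 2 biological replicates, so no comparison between conditions could be made. The questions addressed here are how far the replicates shared their peaks, where in the genome the peaks lay, and which genes and sequences lay under them.

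The deposited list for replicate 1 held 29600 peaks and that for replicate 2 held 26067 peaks. The list called on both replicates together held 26266 peaks, of which the authors kept 1667 with an irreproducible discovery rate threshold. These 1667 peaks, called the thresholded peaks from here on, were the 1667 peaks of highest signal in the joint list, with signal values from 91.0 to 841. Of them, 1502 were 420 bp wide. Together they covered 0.654% of the nuclear genome. The signal value is the authors' own score per peak and was used to rank and describe peaks within a list and to correlate the replicates at shared peaks. The read depth behind the lists was not used here.

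The strongest thresholded peak stood upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Its signal was 841 in the joint list, and the replicates' own signals at this place were 432 and 410.1. Other ribosomal protein genes at strong peaks were rpl-20 (signal 643), rpl-15 (575) and rpl-35 (455), all among the 20 strongest. The second place, with a signal of 810.0, was the promoter shared by tasp-1 and K01G5.10, and the seventh, with a signal of 546, was that shared by nhl-2 and tag-340. The gene nhl-2 encodes a cofactor of microRNA-mediated silencing. Among the 20 strongest peaks, 10 lay in a promoter window, 6 in an intron and 4 outside protein-coding genes.

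The peak at rpl-3 (WBGene00004414) ran from 3867383 to 3867733 on chromosome III of the ce11 assembly. Its summit at 3867559 lay 295 bp upstream of the annotated 5′ end, and the 31 bases centred on it read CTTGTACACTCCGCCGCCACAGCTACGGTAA. The peak between nhl-2 (WBGene00003598) and tag-340 ran from 4899789 to 4900072 on chromosome III, with its summit 837 bp upstream of nhl-2 and 586 bp upstream of tag-340. The sequence at its summit was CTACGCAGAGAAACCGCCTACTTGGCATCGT, inside the annotated non-coding RNA gene F26F4.14. The peak at tasp-1 ran from 10759080 to 10759419 on chromosome III, with the summit 46 bp upstream of the 5′ end.

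The other promoter peaks among the 20 strongest stood at cdc-48.1, which encodes an ATPase of protein quality control (signal 500.3), at puf-9, a Pumilio-family RNA-binding protein gene (445), at ftt-2 (439), and between ipla-6 and mif-4 (435). The peak in the promoter of rpl-20 also lay in that of Y17G9B.5, and the peak in the promoter of rpl-15 in that of K11H12.8. The peaks in introns were in pqn-41, which held a pair of them (signals 591 and 467), ppfr-1 (528), mom-1 (452, with cest-16 as the nearest 5′ end), epg-9 (439) and pxn-1 (438). The peaks outside protein-coding genes had sup-26 (574), T04C4.3 (529), cmd-1, the calmodulin gene (519.7), and W02H3.3 (461) as their nearest genes, at distances of 1962, 2757, 4772 and 3965 bp. The peak near T04C4.3 ran from 2219468 to 2219779 on chromosome IV and carried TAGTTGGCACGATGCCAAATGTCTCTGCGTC at its summit.

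Nearly all thresholded peaks were present in both replicates. Of the 1667 summits, 1647 (98.8%, Wilson 95% interval 98.2 to 99.2) lay inside a peak of each replicate's own list, and 0 lay in neither. Replicate 1 held 99.5% of them and replicate 2 held 99.3%. Across the shared peaks, the replicates' own signal values had a Spearman rho of 0.567 and, on the log2 scale, a Pearson r of 0.67. These are correlations across peaks of 1 pair of samples, and peaks are not independent replicates, so no p-value is given. The peaks had also been selected by the authors with the IDR threshold and were the 1667 of highest joint signal. How this selection moved the correlations was not tested. Among the full lists, 11420 of the 29600 peaks of replicate 1 (38.6%) had their summit inside a peak of replicate 2. When only the 1667 strongest peaks of each replicate were used, 65.6% of the thresholded summits lay in a peak of both.

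Thresholded summits were concentrated just upstream of protein-coding genes. A promoter window, from 1000 bp upstream to 200 bp downstream of an annotated protein-coding 5′ end, held 751 of the 1667 summits (45.1%, Wilson 95% interval 42.7 to 47.4). Random placement within the same chromosome gave 25.7% on average and 29.1% at most in 1000 placements (two-sided permutation p = 0.002, the smallest these placements can give). Of these 751 summits, 89.5% lay upstream of the nearest 5′ end, at a median distance of 296.5 bp. The window is itself mostly upstream, and of the summits that random placement put in it 73.3% lay upstream on average and 76.2% at most in 20 placements, a comparison added after the data were seen. Introns held 323 summits (19.4%, 17.6 to 21.3), against 27.3% under random placement. Coding exons held 33 (1.98%, 1.41 to 2.77) against 18.6%, and sequence outside protein-coding genes and their promoter windows held 537 (32.2%, 30.01 to 34.5) against 25.5%. Peaks were treated as independent in these tests, and all intervals here cover counting error only.

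**Figure D1:**
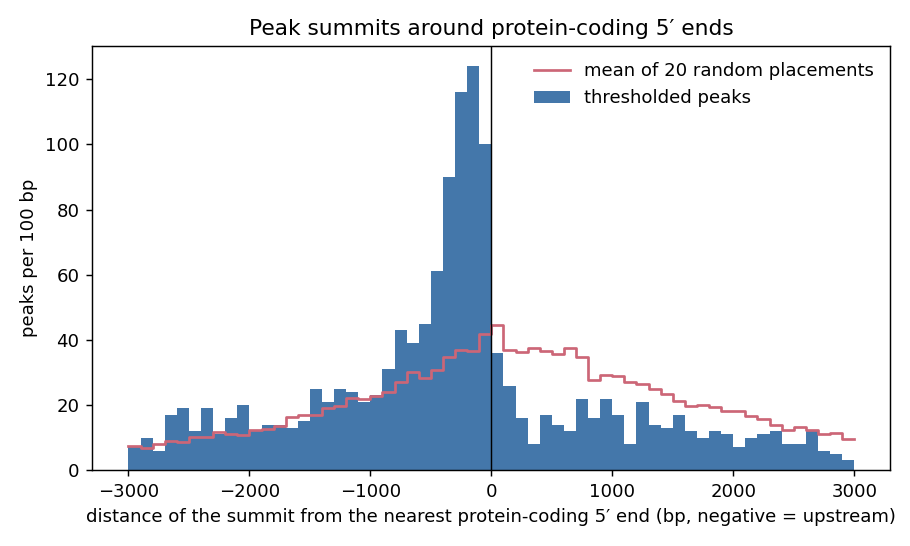
Distance of each thresholded summit from the nearest protein-coding 5′ end, in bp with negative values upstream, as peaks per 100 bp (bars), with the mean of 20 random placements (line). The highest bar, 124 peaks, lies 200 to 100 bp upstream, where random placement gave 36.5.

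The X chromosome held more thresholded peaks than its length would give, and chromosome V held fewer. X carried 417 of the 1667 summits (25.02%, Wilson 95% interval 22.99 to 27.1) but makes up 17.7% of the nuclear genome (two-sided exact binomial p = 5.86e-14, adjusted p = 3.51e-13 over the 6 chromosomes). Chromosome V carried 273 (16.4%, 14.7 to 18.2) for 20.9% of the length (adjusted exact p = 1.17e-05), and IV 248 (14.9%, 13.2 to 16.7) for 17.4% (adjusted p = 0.011). Chromosome III was above its share, with 264 (15.8%, 14.2 to 17.7) for 13.7% (adjusted exact p = 0.0233). The 6 shares sum to the whole, so the excess on X lowers those of the autosomes, and the tests did not allow for this. Per Mb, X held 23.5 summits, III 19.2, I 15.6, II 15.1, IV 14.2 and V 13.0. Chromosomes I and II did not pass the threshold of 0.05 (adjusted exact p = 0.304 and 0.131). On X, 63.1% of the peaks lay outside promoter windows.

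On the autosomes, peaks lay towards the chromosome centres. The middle 50% of each autosome held 842 of 1250 autosomal summits (67.4%, Wilson 95% interval 64.7 to 69.9), against 50.01% under random placement (two-sided permutation p = 0.002, the smallest the 1000 placements can give). Peaks near tRNA genes made up part of the X excess. Without the 177 peaks within 500 bp of a tRNA gene, the X share was 21.3% (exact p = 3.58e-04), a setting chosen after the data were seen.

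With the promoter window used here, promoters of genes for protein synthesis and folding were bound far more often than those of other genes. Lists of general function were included beforehand because such genes are often bound in any chromatin immunoprecipitation of this kind. No other factor's data were analysed, so whether this binding is particular to SOMI-1 was not tested. Of 19973 protein-coding genes, 867 (4.34%) had a thresholded summit in their promoter window. Of 81 ribosomal protein genes, 26 were bound (32.1%, Wilson 95% interval 22.9 to 42.9, adjusted exact p = 6.09e-15), led by rpl-3, rpl-20, rpl-15 and rpl-35. Of 60 heat shock and chaperone genes, 15 were bound (Wilson 95% interval 15.8% to 37.2%, adjusted exact p = 2.77e-07). Among these were hsp-1, a cytosolic Hsp70 gene (signal 418), the mitochondrial chaperonin gene hsp-60 (316), hsp-90 (237) and dnj-13 (235.2). Of 29 translation factors, 6 were bound (20.7%, 9.85 to 38.4, adjusted exact p = 0.0053), including eef-1A.2 (191), eif-3.C (179), eef-1G (173) and eef-1A.1 (157). Of 36 genes of mitochondrial respiration, 7 were bound (19.4%, 9.75 to 35.03, adjusted exact p = 0.00393), with cox-5A (374), cox-5B (278), sdha-1 (155) and cox-6B (139) at the front.

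Genes of developmental timing and of the microRNA machinery were also bound more often than other genes. Of 16 heterochronic genes, which set the order of larval cell fates, 6 were bound (37.5%, 18.5 to 61.4, adjusted exact p = 2.41e-04). They were nhl-2 (signal 546), lin-66 (148), lin-46 (142), kin-20 (137), lin-14 (127) and lep-2 (124). Of 13 genes of the microRNA machinery, 4 were bound (30.8%, 12.7 to 57.6, adjusted exact p = 0.00614). These were nhl-2, which both lists hold, ain-1, a partner of Argonaute (signal 292), vig-1 (219.7) and the RNA helicase gene cgh-1 (107). Several of these summits lay far from the 5′ end, at 936 bp upstream for ain-1, 837 bp for nhl-2 and for lin-46, and 790 bp for cgh-1.

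With the thresholded peaks and the promoter window used here, none of the tissue lists passed the threshold of 0.05. In the muscle list 3 of 28 genes were bound (10.7%, 3.71 to 27.2, adjusted exact p = 0.2), namely mup-2, tnt-2 and unc-112 (signals 114, 106 and 105). In the pan-neuronal list 3 of 24 were bound (12.5%, 4.34 to 31.0, adjusted exact p = 0.169), namely egl-21, maco-1 and unc-14 (119.7, 111.5 and 99.3). In the list for epidermis and seam, the lateral skin cells, vab-10 was bound (98.8) as 1 of 20 (adjusted exact p = 0.758). None of the 24 intestinal genes, 41 germline genes or 31 major sperm protein genes was bound, which leaves room for shares of up to 13.8%, 8.57% and 11.03% by the Wilson intervals. Their adjusted p-values were 0.758, 0.606 and 0.758.

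Genes of the cuticle and of molting showed no excess. Of 174 cuticle collagens, 3 were bound (1.72%, 0.588 to 4.95, adjusted exact p = 0.169), and col-159 and col-160 shared a single peak (signal 157), with col-185 (140.4) as the other. Of 24 molting genes, myrf-1, a membrane-bound transcription factor gene, was bound (165), as 1 gene (4.17%, 0.739 to 20.2, adjusted exact p = 1). Of 274 nuclear hormone receptors, 18 were bound (6.57%, 4.195 to 10.1, adjusted exact p = 0.169), led by nhr-68 (337), nhr-48 (236), nhr-34 (186) and nhr-35 (181). Of 86 homeobox genes, 3 were bound (adjusted exact p = 1), namely ceh-38, ceh-20 and unc-42 (132, 111 and 99.3). In the vacuolar ATPase list 3 of 21 were bound (14.3%, 4.98 to 34.6, adjusted exact p = 0.169), namely vha-8, vha-12 and vha-1 (159.6, 143 and 108). Among 31 proteasome genes only rpn-3 (189.7) and among 72 histone genes only his-37 (368) were bound (adjusted exact p = 1 and 0.58). The transgene list, somi-1 and unc-119, had 1 of 2 bound (adjusted exact p = 0.169).

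**Figure D2:**
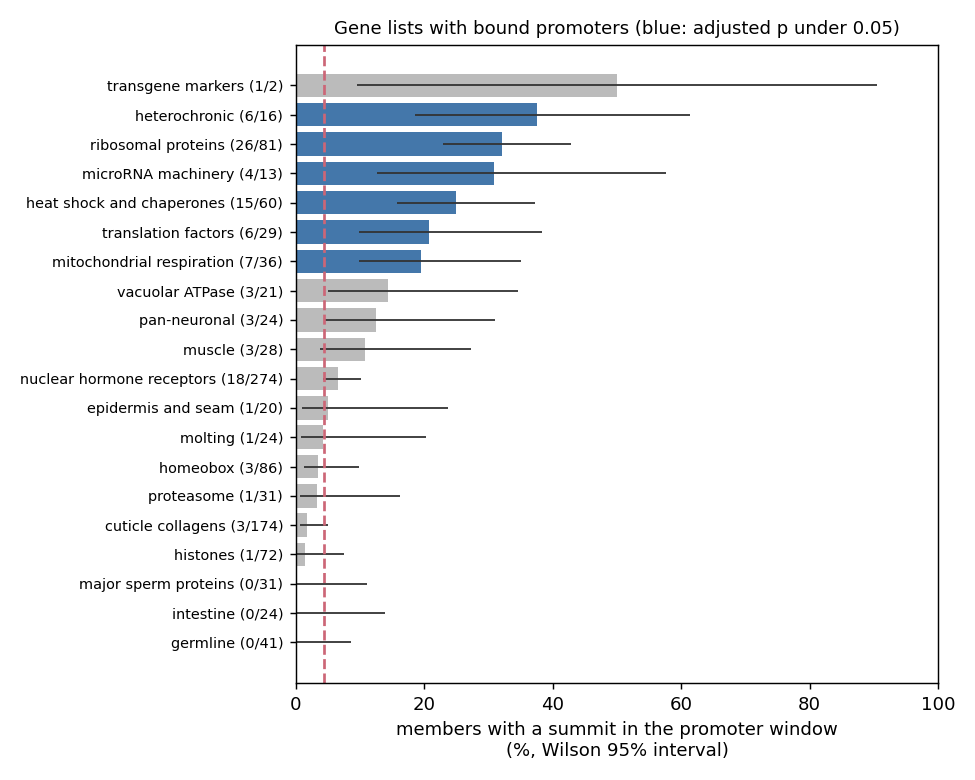
Share of the members of each of the 20 gene lists with a thresholded summit in the promoter window, in percent with Wilson 95% intervals. The dashed line marks the 4.34% of all protein-coding genes, and the 6 lists in blue lie above it with an adjusted p under 0.05, from 19.4% to 37.5%.

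The p-values come from two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 20 lists. Genes with more annotated 5′ ends had more sequence in which a summit could fall, and the tests did not allow for this. The summits counted for kin-20, hsp-90 and cox-6B, for example, lay within the gene, upstream of an internal 5′ end. Genes of divergent promoters share peaks, and 163 of the 751 promoter peaks lay in windows of more than 1 gene. Several calls depended on how a peak was assigned to a gene. With a window of 500 bp upstream to 100 bp downstream, 2 of 16 heterochronic genes (adjusted exact p = 0.209) and 1 of 13 microRNA machinery genes (adjusted p = 0.551) were bound. With the nearest 5′ end only, the microRNA machinery (adjusted exact p = 0.278), mitochondrial respiration (adjusted p = 0.12) and heat shock and chaperone lists (adjusted p = 0.278) no longer passed. There 6 of 60 heat shock and chaperone genes (10%) were bound, against 5.08% of all genes. With the unthresholded joint list the microRNA machinery and the translation factors did not pass (adjusted exact p = 0.141 for each), while the proteasome and muscle lists did, in the direction of more binding. The major sperm protein list passed there in the direction of less, with 6.45% bound against 35.002% of all genes (adjusted exact p = 0.00223). The pan-neuronal list passed with the unthresholded list (adjusted exact p = 0.00573), and with 5 of 24 genes bound both for a window of 2000 bp upstream to 500 bp downstream (adjusted exact p = 0.0346) and for the nearest 5′ end (adjusted exact p = 0.0317). The vacuolar ATPase list passed with that wide window alone, with 5 of 21 bound (23.8%, adjusted exact p = 0.0221).

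By the promoter window, the tagged gene itself counted among the bound genes. Extra copies of its stretch in the transgene could also give peaks there, and this was not separated from binding. The promoter window of somi-1 (WBGene00010868, chromosome V, 13386058 to 13391395, minus strand) held 2 thresholded summits. The stronger ranked 614 of 1667 with a signal of 143, and its summit lay 303 bp upstream of the 5′ end. The genes of interest for molting and timing gave a mixed picture. The promoter of lin-14 (X, 11465560 to 11485871), a regulator of early larval fates, held a summit 175 bp upstream of an annotated 5′ end (signal 127, rank 804), and 3 thresholded summits lay within the gene itself, the strongest with a signal of 188. No thresholded summit lay in the promoter windows of unc-119, lin-29 or bed-3, where the nearest lay 53600, 25520 and 48380 bp from the 5′ end. In the unthresholded joint list, bed-3 had a peak in its window at rank 20451 of 26266 and unc-119 at rank 25811, and lin-29 had 7 summits inside the gene but 0 in its window. The microRNA gene mir-84 (X, 16022404 to 16022478) lay 2273 bp from the nearest thresholded summit, which had a signal of 113 and ranked 1023. In the unthresholded list a summit lay 106 bp from mir-84, at rank 6463. The peaks of that list covered 10.4% of the nuclear genome, and how often random placement would put a summit this near was not computed.

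Peaks were dense around somi-1. From 13371058 to 13416057 on chromosome V, each of 9 consecutive bins of 5000 bp held at least 3 summits of the unthresholded joint list, 41 in all, of which 7 were thresholded peaks. The 15000 bp to the right of this stretch held 0 summits and the 15000 bp to the left held 7. The replicates' own lists held 41 and 46 summits in the same stretch. It covers 9 protein-coding genes, among them gcy-34, cut-2 and cutl-1. These bins were laid out after the data were seen, and the named neighbours were chosen after their values were seen.

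**Figure D3:**
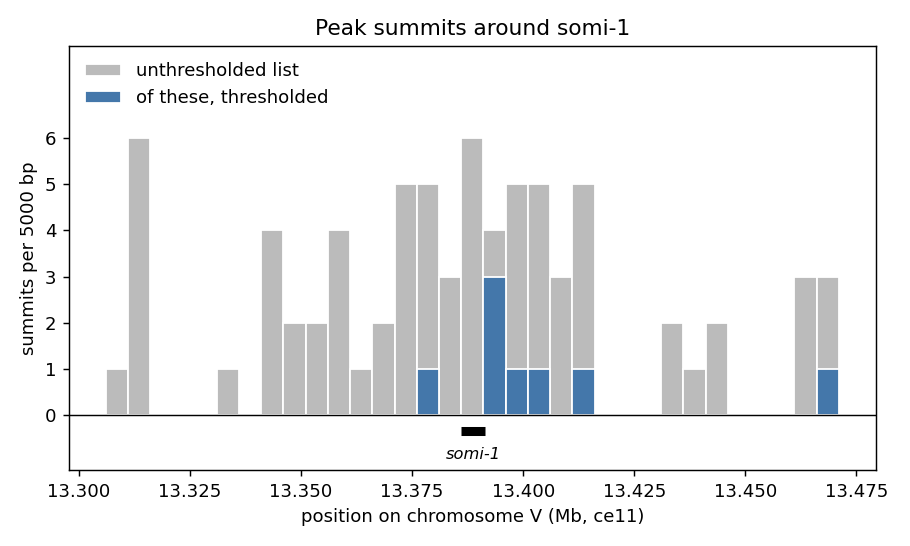
Summits per 5000 bp around somi-1 on chromosome V of ce11, position in Mb, for the unthresholded joint list (grey) and the thresholded peaks among them (blue), with the gene drawn below the axis. The 41 summits between 13371058 and 13416057 are followed by 15000 bp without a summit.

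Genes for small structural RNAs were the most enriched of the 10 non-coding gene classes tested. Of the 1667 summits, 177 (10.6%, Wilson 95% interval 9.23 to 12.2) lay within 500 bp of a tRNA gene, 16.8 times the mean of 10.5 under random placement. Small nucleolar RNA genes, which guide RNA modification, had 85 summits (5.10%, 4.14 to 6.26), 13.9 times the random mean of 6.13. Small nuclear RNA genes had 14 (0.84%, 0.501 to 1.40), 6.94 times the mean of 2.02. The strongest of these stood near sls-2.4 (signal 419), sls-2.1 (365) and, with a shared peak, sls-2.2 and sls-2.3 (276), all genes for spliced leader RNA. At snoRNA genes the strongest peaks were those near C06A1.9 (500.3, also the cdc-48.1 promoter), ZK994.7 (438, in an intron of pxn-1), and C51F7.3 and C51F7.4 (308, a shared peak). The summit near C06A1.9 lay 495 bp from that gene and 152 bp upstream of cdc-48.1. With a distance of 200 bp, 71 summits lay near snoRNA genes.

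Of the 612 tRNA genes, 202 (33.01%) had a thresholded summit within 500 bp. The class was planned because tRNA genes are a usual place of unspecific signal. The strongest stood 272 bp from WBGene00022939 (X, 8036685 to 8036757, signal 350.2). It was an exception in its distance, since 176 of the 177 tRNA-near summits lay within 200 bp of a tRNA gene. The next stood between WBGene00023110 and WBGene00023111 (X, 3036164 to 3036235 and 3035976 to 3036047, signal 262), and 8 bp from WBGene00022903 (IV, 5967160 to 5967232, signal 250.3). Of the 200 strongest thresholded peaks, 4% lay within 500 bp of a tRNA gene, against 10.6% of all 1667. This difference was not tested. On X, 120 of 276 tRNA genes had a summit (43.5%, 37.8 to 49.4), against 82 of 336 on the autosomes (24.4%, 20.1 to 29.3, two-sided Fisher's exact p = 7.61e-07). That comparison was added after the data were seen. It counted tRNA genes as independent, although neighbouring genes can share a summit and identical copies can share reads. It was not split by copy number.

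MicroRNA genes had 14 summits within 500 bp (0.84%, 0.501 to 1.40), 3.22 times the random mean of 4.34. The strongest stood 249 bp from mir-54 and also near mir-55 and mir-55b (X, signal 237), and 173 bp from mir-80 (III, 209.9). Long intergenic RNA genes had 21 summits (2.90 times random) and the broad class of other non-coding RNA genes had 440 (26.4%, 24.3 to 28.6, 3.69 times random), with F26F4.14, F16A11.7 and W06B11.7 holding the strongest (546, 528 and 445). F16A11.7 is annotated as a pair of genes on opposite strands. Genes for piRNAs, the small RNAs of the germline, had fewer summits than random placement gave, 49 against a mean of 71.2, and so had pseudogenes, 22 against 79.1. Antisense RNA genes (7 summits, adjusted permutation p = 0.0888) and ribosomal RNA genes (0 summits of 1667, which allows a share of up to 0.23% by the Wilson interval, adjusted p = 1) did not pass the threshold.

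The 8 classes that passed each had a two-sided permutation p of 0.002, the smallest that 1000 random placements within the chromosome can give, and an adjusted p of 0.0025 with Benjamini-Hochberg adjustment over 10 classes. Random placement did not keep the closeness of the summits to promoters or chromosome centres, so a class may pass through its position there. In the simulated set with planted features, 3 of 10 classes were called, more than had been planted. Many of these genes have near-identical copies, so that reads can be shared between them, and 20.9% of the summits near tRNA genes also lay in a protein-coding promoter window.

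**Figure D4:**
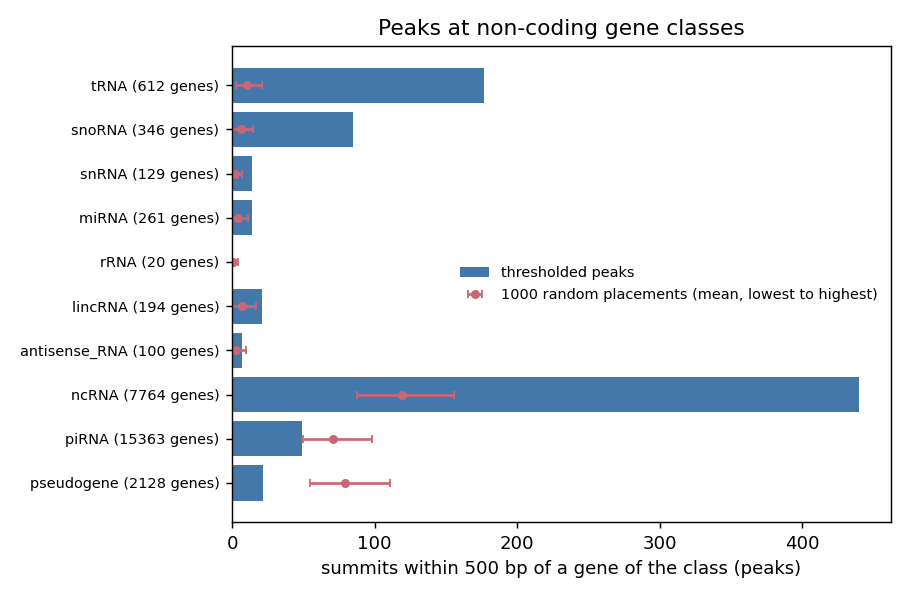
Thresholded summits within 500 bp of a gene of each non-coding class (bars, number of peaks), with the mean and the lowest to highest count of 1000 random placements (points and bars). The bars for tRNA, 177, and snoRNA, 85, extend past the highest random counts of 21 and 15.

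Summits carried short sequence words that were less frequent in their own flanks. The word GACGCA, on either strand, occurred in 11.5% of the 101-bp summit windows on the chromosomes kept for testing (II, IV and X, 895 peaks, Wilson 95% interval 9.58 to 13.8), against 1.62% of windows centred 300 bp to either side. That was 7.10 times as often (one-sided exact sign test, adjusted p = 2.93e-19). The overlapping word ACGCAG reached 12.6% against 1.62%, and AGACGC 11.5% against 1.73%. AGAGAA was the most frequent of the 40 words tested, at 24.5% against 11.5%, and the GA repeat GAGAGA stood in 22.1% of summit windows against 7.15% of flanks (adjusted exact p = 2.93e-19). The palindrome CACGTG, a core bound by many bHLH transcription factors, was at 7.82% against 1.45% (adjusted exact p = 1.23e-11), and CGCGCC at 6.26% against 1.06% (adjusted p = 7.42e-10).

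All 40 words taken from the discovery chromosomes (I, III and V) passed the test on II, IV and X with Benjamini-Hochberg adjustment. Summit windows were richer in G and C than their flanks, at 45.8% against 35.4% on the left and 35.3% on the right. Against windows of matched GC content from promoters without a peak, a control added after the data were seen, 37 of the 40 words passed. GACGCA was then at 5.03% of control windows (adjusted exact p = 3.00e-07), GAGAGA at 7.26% (adjusted p = 7.10e-21), CACGTG at 4.13% (adjusted p = 0.00421) and CGCGCC at 3.91% (adjusted p = 0.00301). CGCCGC, GCCGCC and CGCCAG did not pass (adjusted exact p = 0.274, 0.853 and 0.212).

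**Figure D5:**
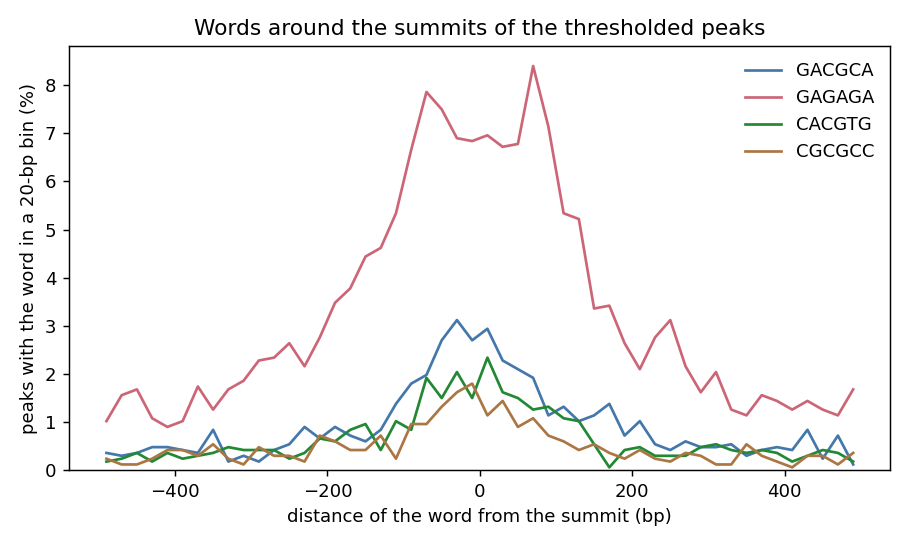
Share of the thresholded peaks, in percent, with each of 4 words in bins of 20 bp, by distance from the summit in bp. GACGCA peaks at 3.12% in the bin 40 to 20 bp before the summit, and GAGAGA reaches its highest value, 8.40%, in the bin 60 to 80 bp after it.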

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

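Merging overlapping peaks, leaving out peaks near tRNA genes and the GC-matched word controls were chosen after the data were seen, and the other alternatives before. The promoter, X and chromosome centre shares kept their direction and stayed past the threshold under every alternative run for them. Replaced by the 1667 strongest peaks of a single replicate, the promoter share ran from 43.2% to 46.4%, the X share from 23.3% to 23.6% and the centre share from 65.9% to 67.6%. In the unthresholded list they were 31.4%, 20.8% and 60.4%. The word counts stayed between 37 and 40 of 40 under all alternatives, but the excess of GACGCA varied in size. From a single replicate its summit share ran from 10% to 11.2% and its flank share from 1.40% to 2.42%. It was 11.5% against 3.91% with flanks 200 bp away and 3.81% against 1.99% in the unthresholded list.

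The replicate overlap of 98.8% moved to 92.9% with reciprocal overlap of at least 50%, to 92.9% with summits within 100 bp, and to 65.6% when only the 1667 strongest peaks of each replicate were used. The last is a stricter comparison by construction. The 6 lists called higher became 4 with the narrow promoter window, 4 with the nearest 5′ end only, 8 with the wide window and 7 with the unthresholded list. The proteasome list, below all genes in the thresholded list with 1 of 31 bound, was above them at 64.5% against 35.002% in the unthresholded list and passed there. It was also above them, without passing, at 6.45% to 9.68% in a single replicate's strongest peaks and at 9.68% with the wide window, so its place below has little weight. Counts of other small lists moved too when a single replicate was used, to 5 and 6 of 174 collagens, 1 and 3 of 72 histones and 1 and 3 of 86 homeobox genes, with none past the threshold. In the unthresholded list the muscle list was at 92.9% and the pan-neuronal list at 66.7%, both now past the threshold, and major sperm proteins at 6.45% passed as lower. The 6 non-coding classes called higher became 7 in the stronger 833 peaks, where antisense RNA passed, and stayed 6 under the other alternatives. Their size over random moved more. For tRNA genes it was 15.02 to 15.6 times from a single replicate, 34.9 at 200 bp and 3.42 in the unthresholded list, and for snoRNA genes 12.7 to 13.1, 23.8 and 2.71.

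Of 51 named protein-coding genes, 46 kept their bound state in the strongest peaks of replicate 2 alone and 48 in those of replicate 1 alone. The genes lost were ceh-20, mup-2, unc-14, unc-42 and vha-1 in the first case and tnt-2, unc-112 and vab-10 in the second. With the narrow window 12 were lost, among them nhl-2, ain-1, cgh-1, lin-46 and lin-66, and with the nearest 5′ end 11. Read depth was not used here, so its effect on which weak peaks were called is unknown.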

Other observations

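GACGCA was unevenly spread over the thresholded peaks. It occurred in the summit window of 116 of 751 promoter peaks (15.4%, Wilson 95% interval 13.0 to 18.2), 62 of 537 intergenic peaks (11.5%, 9.11 to 14.5) and 23 of 323 intron peaks (7.12%, 4.79 to 10.5). Near tRNA genes 7 of 177 peaks had it (3.95%, 1.93 to 7.94), against 199 of 1490 elsewhere (13.4%, 11.7 to 15.2, two-sided Fisher's exact p = 9.17e-05). On X, 26 of 417 peaks had it (6.24%, 4.29 to 8.98), against 180 of 1250 on the autosomes (14.4%, 12.6 to 16.5, exact p = 4.43e-06), and the difference held among peaks away from tRNA genes (p = 8.32e-05). The stronger 833 peaks had it in 14.05% and the weaker 834 in 10.7% (exact p = 0.0374). Among words of 8 bases, tested in the same way, GAGACGCA stood in 6.15% of the test summit windows against 0.223% of flanks (adjusted exact p = 1.55e-14), and AGACGCAG in 6.37% against 0.279% (adjusted p = 2.97e-14). These comparisons were chosen after the data were seen, and the 4 comparisons of peak groups are not adjusted for one another.

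The share of tRNA genes with a peak was compared between amino acids. Of 13 genes for cysteine tRNA, 10 had a thresholded summit within 500 bp (76.9%, 49.7 to 91.8), against 33.01% of all tRNA genes (two-sided Fisher's exact test, adjusted p = 0.0298 over 22 groups). No other group passed 0.05, and no test over all groups together was run. The timing microRNA genes lin-4, mir-48 and mir-241 had no thresholded summit within 500 bp. The gene let-7 was not examined, as that name was not a symbol of the annotation used. In the unthresholded list the nearest summits lay 363 bp from lin-4 (rank 6327 of 26266), 172 bp from mir-48 (rank 3374) and 658 bp from mir-241 (rank 2336). These distances were not set against random placement, and the peaks of that list covered 10.4% of the nuclear genome.

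Explanations were weighed for 3 patterns. Of their tests, those of read number on X and of tRNA genes as the source of the X excess were chosen after the results were seen, and the others before. The bound for the test of read number was also made stricter after its value was seen. No biological explanation was tested for the patterns on X and at tRNA genes, since the design has a single group, and signal common to many factors at accessible chromatin was not tested because no other factor's data were analysed here.

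The X chromosome held 25.02% of the thresholded peaks for 17.7% of the length. A larger part of X outside promoters cannot be the whole cause, since 20.5% of the 751 promoter peaks lay on X (17.8 to 23.5), which has 14.7% of promoter sequence (two-sided exact binomial p = 1.78e-05). The many tRNA genes of X may account for part of the excess, as the X share fell to 21.3% (19.3 to 23.4, n = 1490) without peaks near tRNA genes, but it stayed above the share of length (exact p = 3.58e-04). More reads from X stay open, because the 24599 joint peaks below the threshold had an X share of 20.5% (20.01 to 21.02), between the share of length and that of the thresholded peaks. The interval of 19.3 to 23.4 without peaks near tRNA genes holds this 20.5%, and these explanations were not tested together.

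Peaks stood near 33.01% of tRNA genes. Reads shared between identical copies are unlikely to be the whole cause. Of 140 tRNA genes with a sequence found once in the genome, 18.6% had a peak (13.0 to 25.8), above the highest of 1000 random placements, 6.43%, and the share was 17.4% among the 109 of them with no multi-copy tRNA gene within 1000 bp, a subset chosen after the data were seen. Shared reads could still add to the 37.3% (33.04 to 41.7) seen at the 472 genes with identical copies, as this difference was not followed further. Copies that differ by a few bases were not set apart, so reads shared between near-identical copies stay open. Neighbouring protein-coding promoters are not the source of most of these peaks, since 20.9% of the 177 tRNA-near summits lay in such a window, against 47.9% of all other summits (two-sided Fisher's exact p = 2.51e-12).

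The tagged gene somi-1 carried peaks in its own promoter, but so did the sequence around it. Within 20000 bp to either side of somi-1 the unthresholded joint list held 39 summits, against a median of 10 and a 95th percentile of 22 over 4176 equal windows on chromosome V. A candidate explanation is extra copies of this stretch in the transgene, which would raise the reads from all of it. Binding of SOMI-1 at its own gene stays open as well, since the test does not separate extra DNA from binding.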
